A study of Mus musculus with 6 samples.

How the data were processed

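Total RNA from 6 samples of the mouse colon carcinoma line MC38 was measured on single-colour Illumina mouse bead arrays, all 6 on 1 chip. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase I treatment, checked on a Bioanalyzer and amplified to biotin-labelled cRNA. The deposited probe signals are intensities on a linear scale that had not been normalized, and their medians of 90.2 to 97.4 show that background had not been subtracted. The deposited detection p-values compare each probe with the negative control beads of its own array, per the file headers. A second deposited table holds log2 values. These log2 values equalled quantile-normalized log2 signals without background subtraction to within 0.00203 on every probe, so their scale and direction are known from that match. The software that summarised the bead signals is not given in the sources used here.

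The groups come from the sample titles. There were 2 arrays each of cells starved of serum for 16 h (unstimulated), cells starved for 16 h and given S100A8/A9 at 10 µg/mL for 6 h (stimulated), and cells in normal growth medium (control). The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Array position on the chip followed the groups, so position and group cannot be told apart. No 2 arrays were identical throughout: 88 to 134 of 45281 signals were equal in a pair.

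Signals were analysed in R 4.3.3 with limma 3.58.1. Background was corrected with the neqc function, that is normexp with the negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Of 45281 probes, 34885 had 1 gene symbol in the platform annotation used, 18 had several and 10378 had none. Probes without a symbol are unnamed here and stayed out of the main tests, and list symbols were updated through a table of current mouse gene names and synonyms. A probe was tested if its detection p-value was below 0.01 on at least 2 of the 6 arrays, which left 16355 probes, 14157 of them with 1 symbol. For each of the 8909 genes so covered, the probe with the highest mean over all 6 arrays was used, and 3572 of these genes had more than 1 detected probe. Over the named genes, 8 of 8, 40 of 41 and 44 of 44 other detected probes had the sign of the chosen probe in the 3 comparisons below, and 0, 17 and 15 differed from it by more than 1.5-fold.

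A linear model with 1 mean per group was fitted to all 6 arrays, which leaves 3 residual degrees of freedom, and limma's empirical Bayes step added 6.00 prior degrees of freedom. The comparisons were stimulated versus unstimulated, unstimulated versus control and stimulated versus control. Adjusted p-values are Benjamini-Hochberg values over the 8909 genes, and a gene was called changed at an adjusted p below 0.05. Where a gene was not detected on either array of a group, only a bound is given: the bright group's mean over the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

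Before the data were examined, 23 gene lists were fixed. They covered NF-kB pathway genes and targets, chemokines, cytokines and growth factors, acute phase and antimicrobial genes, interferon-stimulated genes, MHC class I antigen presentation, immediate early genes and MAPK feedback, SRF and YAP targets with the actin cytoskeleton, mitosis, DNA replication, cholesterol synthesis and uptake, fatty acid synthesis, FOXO targets and quiescence, ATF4 and ER stress, glycolysis and hypoxia, matrix with proteases and migration, S100A8/A9 receptors and adaptors, zinc and copper handling, ribosome biogenesis, oxidative stress (NRF2) targets, and markers of epithelial cells, of fibroblasts and of leukocytes with endothelium. The 21 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry.

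Named genes followed a rule fixed before the data were examined. It took, per comparison, the 10 largest rises and 10 largest falls among genes called changed, with both arrays of 1 group above both of the other and detection on both arrays of the higher group. It added up to 4 called members of each list past camera's threshold (2 if none was called), up to 2 called members of each other list, and always Tlr4, Ager, S100a8 and S100a9. Symbols of provisional genes were counted but not named. A list's median is over its tested members.

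The steps were tested on simulated data drawn from the gene means and spreads of these arrays. In stimulated versus unstimulated, 34.3% of 1.5-fold changes, 92.5% of 2-fold changes and 100% of 4-fold changes were called, with 10 false calls among 8909 genes. The shares were 44.8%, 94.0% and 100% with 4 false calls in unstimulated versus control, and 34.3%, 98.5% and 100% with 8 false calls in stimulated versus control. These simulations changed 67, 67 and 66 genes by the 3 sizes, and the adjusted threshold is stricter where fewer genes change, as with the 7 called in stimulated versus unstimulated. In a single simulation over 21 lists, the 1 list shifted by 0.5 on the log2 scale was called and 0 others were. Simulated genes varied independently of each other. The simulation therefore cannot show how often a list is called falsely when its genes are correlated.

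Alternatives covered the background correction, the normalization between arrays, the deposited log2 values, the detection filter, the probes of a gene, the replicate number as a block, the arrays in the fit, the variance model, array weights, a size threshold and leaving out each array in turn. Array number limits the precision: there were 2 per group, with 32.9% to 35.7% of probes detected on each. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.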

Results

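The data were expression profiles of MC38 cells, a mouse colon carcinoma line, on 6 bead arrays. Cells were kept in normal growth medium (control), starved of serum for 16 h (unstimulated), or starved for 16 h and given 10 µg/mL of S100A8/A9 for 6 h (stimulated), with 2 arrays per group. S100A8/A9, also called calprotectin, is a calcium- and zinc-binding protein pair secreted by neutrophils and monocytes, and a ligand of the receptors encoded by Tlr4 and Ager. Between 14877 and 16176 of 45281 probes were detected per array. Across genes, replicate arrays correlated at r = 0.991 to 0.992, unstimulated with stimulated arrays at 0.989 to 0.990, and control arrays with the other 4 at 0.961 to 0.963. The first principal component held 70.2% of the variance and separated control arrays from the rest, and the second held 9.71% and separated stimulated from unstimulated arrays. The third held 7.44% and set the 2 stimulated replicates apart (11.9 and -14.5).

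The comparison of stimulated with unstimulated cells asked which genes S100A8/A9 switched on in these tumor cells. In it, 7 of 8909 genes rose and 0 fell (limma, Benjamini-Hochberg). The labels do not say whether unstimulated cells were kept for the same further 6 h, so these values may include 6 h more of reduced serum. Cxcl1, a chemokine that attracts neutrophils, rose 5.43-fold (log2 fold change 2.44 ± 0.16 SE, n = 2 arrays per group, adjusted p = 0.000417). Lcn2, the iron-sequestering protein lipocalin 2, was not detected on either unstimulated array and rose at least 4.99-fold (adjusted p = 0.000417), and Slc39a10, a zinc importer, rose 5.18-fold (2.37 ± 0.17, adjusted p = 0.000536). Nfkbiz, a nuclear regulator of NF-kB target genes, rose 3.65-fold (1.87 ± 0.15, adjusted p = 0.000934) and Zc3h12a, an RNase that degrades inflammatory mRNAs, rose 3.45-fold (1.79 ± 0.19, adjusted p = 0.00761). Fas, a death receptor, rose 2.71-fold (1.44 ± 0.14, adjusted p = 0.00539). Fndc7, not detected on either unstimulated array, rose at least 2.05-fold (adjusted p = 0.00761).

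Inflammatory gene groups rose with them. Of 21 lists tested with camera at the preset correlation, 6 moved upward and 0 downward. With an estimated correlation 3 of the 6 passed (adjusted p = 0.0462 for each) and 3 did not (adjusted p 0.0907 to 0.321). All 10 tested chemokines, of 25 listed, had estimates above 0 (median log2 fold change 0.66, camera adjusted p = 1.14e-13). Cxcl9 met the detection filter only through the stimulated arrays, which favors an estimate above 0. Cxcl1 was the only one called over all genes, and 7 rose when adjusted over the list alone. The NF-kB list followed (26 genes, median 0.28, camera adjusted p = 2.59e-09), with Nfkbiz and Zc3h12a called, 2 genes in all, and 8 adjusted over the list alone. Interferon-stimulated genes moved upward as a group (27 genes, median 0.31, camera adjusted p = 1.57e-09) with 0 members called. Adjusted over the list alone, 7 rose and 1, Socs1, fell. Their largest estimates were Oas1g at 1.14 (limma adjusted p = 0.106) and Gbp3 at 1.04 (limma adjusted p = 0.110). These 3 lists were the ones that also passed with an estimated correlation.

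Acute phase and antimicrobial genes (6 tested of 23 listed, median 0.74, camera adjusted p = 6.08e-07) had 1 called member, Lcn2, and 3 adjusted over the list alone. With an estimated correlation the list's camera adjusted p was 0.0907. Lcn2 met the detection filter only through the stimulated arrays, which favors an estimate above 0. MHC class I genes (18 genes, median 0.16, camera adjusted p = 0.00971, estimated correlation adjusted p = 0.229) had 0 called members and 1 adjusted over the list alone, with estimates of 0.93 for Erap1 (limma adjusted p = 0.230) and 0.48 for Tapbp (limma adjusted p = 0.402). Cytokines and growth factors (15 genes, median 0.13, camera adjusted p = 0.0435, estimated correlation adjusted p = 0.321) had 0 by either count, with Lif at 0.90 (limma adjusted p = 0.504) and Bmp4 at 0.54 (limma adjusted p = 0.480). The cytokine list lost its call without unstimulated replicate 2, without stimulated replicate 2 (highest camera adjusted p = 0.388) or without control replicate 2. Without stimulated replicate 2, the camera adjusted p of the MHC class I list was 0.0875.

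Zinc genes moved apart inside their list, which as a whole did not shift (13 genes, median 0.05, mean -0.08, camera adjusted p = 0.954). Adjusted over the list alone, the importer Slc39a10 rose and 3 genes fell: the zinc exporter Slc30a1 (log2 fold change -2.11 ± 0.35 SE) and the metallothioneins Mt1 (-0.92 ± 0.19) and Mt2 (-1.10 ± 0.31). Over all genes these 3 did not pass limma's threshold (adjusted p = 0.0912, adjusted p = 0.151 and adjusted p = 0.334). The size of the fall of Slc30a1 is uncertain, because it was detected on only 1 of the 2 stimulated arrays (log2 intensities 4.73 and 6.03). Its log2 fold change was -1.46 without stimulated replicate 1 and -2.76 without stimulated replicate 2. With all arrays in, it was -1.17 without background correction and -1.46 with a normexp offset of 50. Slc30a1 was among 23 genes with an adjusted p below 0.1, 18 higher and 5 lower. Those of them not called but detected on all arrays compared are given here, so chosen after their values were seen. Above 0 lay the chemokines Ccl2 (1.13), Ccl7 (1.04) and Ccl5 (1.14), Irf9 (0.99), Cyp7b1 (0.94), Grm7 (1.02), the protease inhibitor gene Slpi (1.09), Prl2c3 (0.98) and Fbxo32 (0.99), and below 0 lay Fam180a (-0.99) and Osr1 (-1.25), with limma adjusted p from 0.0527 (Ccl2) to 0.0988 (Ccl5). The receptor Tlr4 was detected on all 6 arrays by 2 of its 3 probes and did not pass (0.25 ± 0.18, adjusted p = 0.769). Ager was detected on at most 1 array by either probe, and the endogenous S100a8 and S100a9 were detected on 0 arrays.

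**Figure D1:**
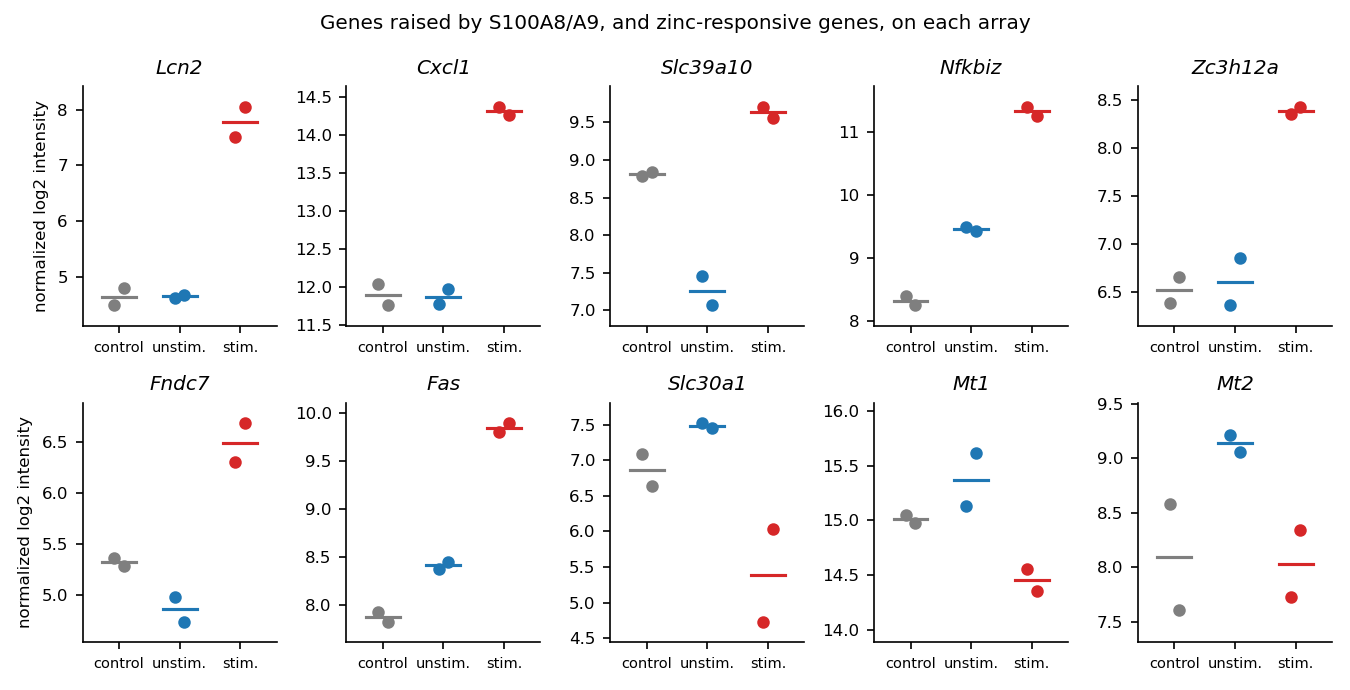
Normalized log2 intensity (vertical axis, scaled per gene) of 10 genes on each array. Points are single arrays and bars are group means of 2 arrays; the first 7 genes rose in stimulated against unstimulated cells, and Slc30a1, Mt1 and Mt2 lay lower there without passing limma's threshold over all genes.

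The other 15 lists did not pass in this comparison. Glycolysis and hypoxia genes came closest (median -0.08, camera adjusted p = 0.0518), followed by S100A8/A9 receptors and their adaptors (median 0.07, adjusted p = 0.0620), ribosome biogenesis (adjusted p = 0.151) and immediate early genes (adjusted p = 0.226). The glycolysis list passed without unstimulated replicate 1 and without stimulated replicate 1, and the receptor list without unstimulated replicate 2 and without stimulated replicate 1 (camera adjusted p 0.0315 to 0.0418). Mitosis, cholesterol, FOXO, ATF4, matrix, NRF2 and fibroblast lists each had camera adjusted p = 0.575, and DNA replication, fatty acid synthesis and the SRF and YAP list each had 0.954. Adjusted over the list alone, 2 FOXO, 2 matrix, 1 ATF4, 1 receptor (Cd14), 1 ribosome biogenesis and 1 fibroblast gene rose. The count of 7 was sensitive to processing: 730 genes had an unadjusted p below 0.05 (338 higher and 392 lower), and median scaling in place of the quantile step gave 8 higher and 7 lower beside the 7 and 0. Cxcl1, Slc39a10 and Nfkbiz passed without any 1 of the 6 arrays. Without unstimulated replicate 1 or without stimulated replicate 1 the count was 4. Zc3h12a passed in 3 of 6 such fits (highest adjusted p = 0.0832), Fas in 4 of 6 (0.0894) and Fndc7 in 2 of 4 (0.206), while Lcn2 passed in all 4 that tested it. Neither Lcn2 nor Fndc7 met the detection filter without a stimulated replicate, so their dependence on a single stimulated array was not tested.

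The comparison of unstimulated with control cells measured the response to reduced serum. It was broad: 1527 of 8909 genes rose and 1219 fell (limma, Benjamini-Hochberg), and 459 rose and 174 fell by 2-fold or more. Interferon-stimulated, MHC class I and cholesterol genes rose as lists, while DNA replication and mitosis genes fell, by camera with a preset and with an estimated correlation (adjusted p = 0.0493 for each with the latter). Another 9 of the 14 lists past camera passed with the preset correlation only (adjusted p 0.0533 to 0.375 with an estimated one). Inmt, an N-methyltransferase gene, was not detected in control cells and rose at least 32.7-fold (adjusted p = 3.48e-07), and at least 6.49-fold on its other detected probe. Prelp and Mgp, which encode extracellular matrix proteins and were not detected in control cells, rose at least 13.4-fold and at least 8.35-fold, and Ogn, which encodes a small proteoglycan, rose 12.9-fold (log2 fold change 3.69 ± 0.17 SE). Gsn, which encodes the actin-severing protein gelsolin, and Ifi27l2a, an interferon-induced gene, rose at least 10.7-fold and at least 7.19-fold from no detection. Fam180a rose by 3.85 on the log2 scale, Mxd4, a MAX-binding repressor, by 3.79 and Lmcd1 by 3.59. Other probes of these genes gave, on the log2 scale, 2.93 and 3.12 for Ogn, 3.06 and 3.01 for Mxd4, 3.50 for Fam180a and 3.48 for Lmcd1. A further Lmcd1 probe gave at least 3.50-fold from no detection in control cells.

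The largest falls included 3 placental prolactin-like (proliferin) genes, Prl2c3 (log2 fold change -2.82 ± 0.17), Prl2c2 (-2.71 ± 0.14) and Prl2c4 (-2.61 ± 0.22), near-identical copies whose separate levels are uncertain because a probe can bind more than 1 of them. Id1 (-2.17 ± 0.24) and Id2 (-2.13 ± 0.31), inhibitors of basic helix-loop-helix factors, fell too, as did Prf1 (-2.63 ± 0.40), Ramp3 (-2.09, its other detected probes -1.48 and -2.51), Zbtb2 (-1.95), the metal transporter Slc11a1 (-1.95) and Pramel4 (-1.82). The adjusted p of these falls ranged from 8.69e-06 for Prl2c2 to 0.00625 for Zbtb2 (limma, Benjamini-Hochberg). Zbtb2 lost its call without unstimulated replicate 2 (adjusted p = 0.0580). Without control replicate 1 or 2, Prf1 was at -1.98 or -3.26 and Zbtb2 at -1.25 or -2.64. Log2 intensities on control replicates 1 and 2 lay apart for Prf1 (12.47 and 11.19), Zbtb2 (11.37 and 9.99) and Pramel4 (10.10 and 9.23). They lay close for Prl2c2 (13.19 and 13.26) and Id2 (7.85 and 7.88).

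Interferon-stimulated genes made the largest group shift. Of 27 tested, 25 rose and 1, Irgm1, fell (median 1.51, camera adjusted p = 5.74e-15), the same counts as adjusted over the list alone. Ifit3 rose by 3.73 (on its other detected probe at least 3.53-fold from no detection in control cells), Rsad2 by 3.25, Cmpk2 by 2.91 and Ifi47 by 2.90 on the log2 scale. Of 18 MHC class I genes, 15 rose by both counts (median 0.80, camera adjusted p = 1.79e-07), among them the peptide loading factor Tapbp (2.05, its other detected probe 1.38), the immunoproteasome subunits Psmb9 (1.86) and Psmb8 (1.49) and the peptide transporter Tap2 (1.54). Of 18 cholesterol genes, 15 rose by both counts (median 1.10, camera adjusted p = 5.05e-08), including Nsdhl (1.74), Mvd (1.67), Lss (1.43) and Fdps (1.39). The other detected probe of Fdps was at 0.47 ± 0.17.

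Growth genes fell. Of 31 DNA replication genes, 25 fell, and 27 adjusted over the list alone (median -0.75, camera adjusted p = 4.30e-12), with the helicase subunit Mcm3 at -1.38, Prim1 at -1.18, Ccne2 at -1.12 and Chaf1a at -1.05. Of 21 mitosis genes, 13 fell, and 15 adjusted over the list alone (median -0.59, camera adjusted p = 3.12e-07), with Ccna2 at -1.19 and Ttk, Aurka and Ube2c at -0.92, -0.92 and -0.89. Ttk lost its call without unstimulated replicate 1 or control replicate 1 (adjusted p up to 0.0651), and Ube2c without either replicate 2 of these groups (up to 0.0860). The interferon, MHC class I, cholesterol, replication and mitosis lists also passed with an estimated correlation (adjusted p = 0.0493 for each). Ribosome biogenesis genes fell in 10 of 14 cases, and 12 adjusted over the list alone (median -0.76, camera adjusted p = 9.83e-07), with Gnl3 at -1.47, Rrp9 at -1.35, Bop1 at -1.01 and Nop2 at -0.98. That list had adjusted p = 0.0533 with an estimated correlation.

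Metabolic and stress groups rose at the preset correlation and lost the call with an estimated one. Fatty acid synthesis genes rose in 9 of 13 cases by both counts (median 0.83, camera adjusted p = 3.20e-05, estimated correlation adjusted p = 0.116), led by Acss2 (2.54), Scd1 (1.07), Scd2 (0.98) and Acly (0.96). Glycolysis and hypoxia genes rose in 11 of 19, and 12 adjusted over the list alone (median 0.64, camera adjusted p = 9.83e-07, estimated correlation adjusted p = 0.0737). Among them, Car9 rose at least 2.08-fold from no detection, Egln3 by 1.69, Pdk1 by 1.48 and P4ha2 by 1.45 on the log2 scale. ATF4 and ER stress genes rose in 13 of 24 by both counts (median 0.50, camera adjusted p = 3.20e-05, estimated correlation adjusted p = 0.100), with Nupr1 at 2.49, Ddit4 at 1.71, Atf5 at 1.61 and Dnajb9 at 1.32. Of 19 FOXO and quiescence genes, 10 rose and 1 fell, and 11 rose and 1 fell adjusted over the list alone (median 0.56, camera adjusted p = 0.000148, estimated correlation adjusted p = 0.0686). Pik3ip1, an inhibitor of PI3 kinase, rose at least 3.65-fold from no detection, Pdcd4 by 1.91, Ccng2 by 1.32 and Fbxo32 by 1.21 on the log2 scale. The other detected probe of Fbxo32 was at -0.09 ± 0.37 and that of Dnajb9 at 0.72 ± 0.15. The other probes of Acss2, Car9 and Egln3, not detected in control cells, gave at least 2.73-fold, 1.43-fold and 1.10-fold. For Pdcd4, other detected probes gave 1.62 and 1.77 on the log2 scale. A further Pdcd4 probe, not detected in control cells, gave at least 1.03-fold.

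Immediate early genes went both ways: 9 of 23 rose and 2 fell, and 10 rose and 2 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.00654, estimated correlation adjusted p = 0.124), with rises of Egr2 (2.55), Dusp1 (1.84), Klf4 (1.24) and Fos (1.21). Of 18 matrix and protease genes, 9 rose and 2 fell, and 10 rose and 2 fell adjusted over the list alone (median 0.54, camera adjusted p = 0.0401, estimated correlation adjusted p = 0.375), with the gelatinases Mmp2 (1.55) and Mmp9 (1.06), the crosslinking enzyme Lox (1.28) and Mmp14 (1.10) higher. That list lost its call without control replicate 1 (camera adjusted p = 0.158). Of 10 fibroblast and mesenchymal markers, 6 rose and 1 fell by both counts (median 0.88, camera adjusted p = 0.00183, estimated correlation adjusted p = 0.0956), with rises of Dcn (1.88), Pdgfrb (1.75), Col3a1 (1.59) and Pdgfra (1.54). Another probe of Dcn, detected in both groups, gave 2.04 ± 0.16, and a further probe was detected on 1 of these 4 arrays. NRF2 targets moved down: 4 of 13 fell and 1 rose, and 5 fell and 1 rose adjusted over the list alone (median -0.20, camera adjusted p = 0.0375, estimated correlation adjusted p = 0.155), with Txnrd1 at -1.49, Osgin1 at -0.90 and Gclm at -0.74 and Nqo1 at 0.68 (its other detected probe 0.16). Osgin1 lost its call without unstimulated replicate 2 (limma adjusted p = 0.0645), Gclm without unstimulated replicate 1 or control replicate 1 (up to 0.0715) and Nqo1 without either control replicate or unstimulated replicate 2 (up to 0.119).

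**Figure D2:**
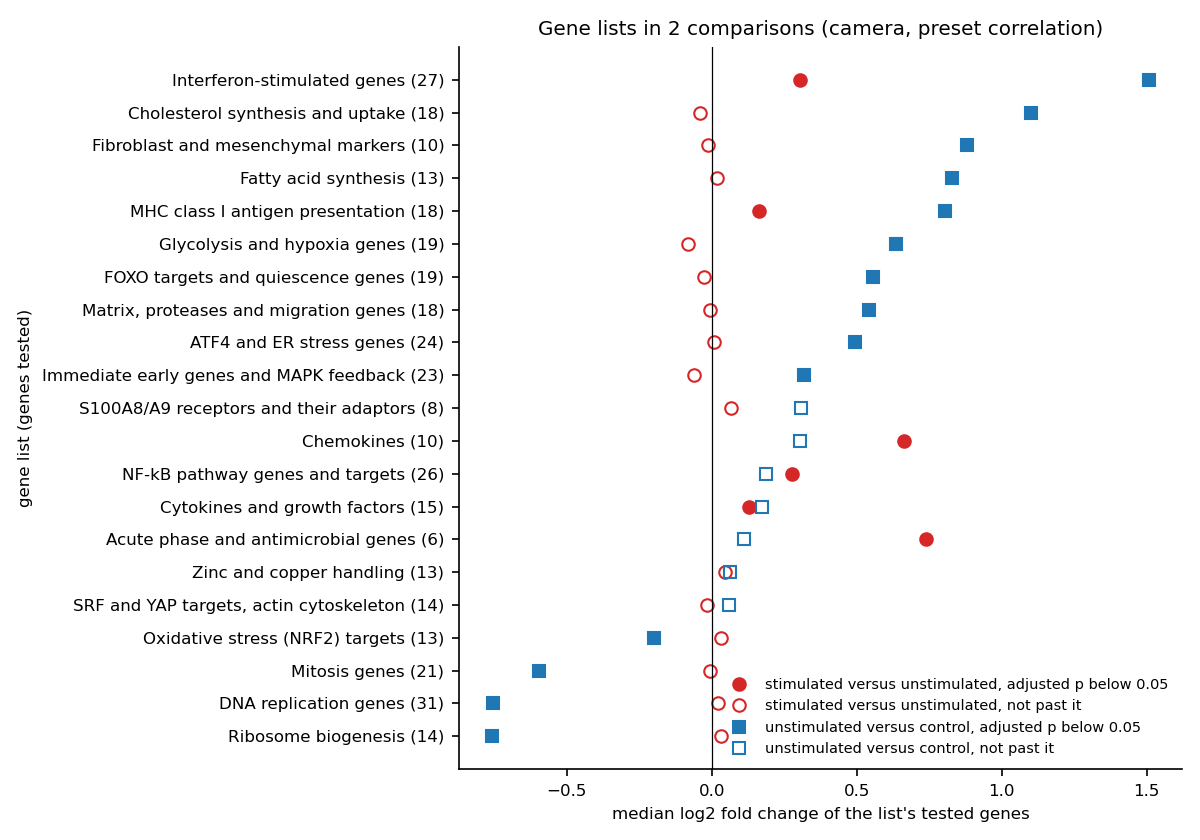
Median log2 fold change (horizontal axis) of the tested genes of each of 21 lists, with the number of genes in brackets. Red circles compare stimulated with unstimulated cells and blue squares unstimulated with control cells; filled symbols passed camera's threshold at the preset correlation, and interferon-stimulated genes lie farthest right at 1.51.

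The other 7 lists did not pass camera, which sets a list against all other genes. The rotation test fry, which sets it against no change, passed 5 of them upward (adjusted p = 0.00356 for NF-kB, 0.00283 for chemokines, 0.0315 for cytokines, 0.0250 for acute phase genes and 0.0456 for receptors). NF-kB genes (9 of 26 rose and 1 fell, 9 and 2 adjusted over the list alone, camera adjusted p = 0.0670) included Nfkbiz at 1.14 and Ptgs2 at -0.97, and chemokines (4 of 10 rose and 2 fell, 5 and 2 adjusted over the list alone, adjusted p = 0.133) included Ccl5 at 2.37 and Ccl9 at 1.73. Cytokines and growth factors (6 of 15 rose and 1 fell, 7 and 1 adjusted over the list alone, adjusted p = 0.186) included Hbegf at -1.59 and Igf2 at 1.43. The ferroxidase gene Cp rose by 3.15 on the log2 scale, the only 1 of 6 acute phase genes to rise by either count (adjusted p = 0.236). Of 8 receptor and adaptor genes 3 rose and 1 fell by both counts (adjusted p = 0.236), with Alcam at -0.81 and Tlr4 at 0.72 (its other detected probe 1.38). Of 13 zinc and copper genes 1 rose and 1 fell, and 0 rose and 1 fell adjusted over the list alone (adjusted p = 0.908), with Slc39a10 at -1.55 and Mt2 at 1.04. Of 14 SRF and YAP targets 0 rose and 2 fell by both counts (adjusted p = 0.595), Ccn1 at -0.60 and Ankrd1 at -0.51, the latter not past the threshold under median scaling. With 1 array left out, calls were lost for Ankrd1 without any of the 4 arrays compared (limma adjusted p up to 0.126), Ccn1 without either control replicate or unstimulated replicate 2 (up to 0.126), Mt2 without control replicate 2 or either unstimulated replicate (up to 0.164), Tlr4 without control replicate 1 or unstimulated replicate 2 (up to 0.111) and Alcam without unstimulated replicate 2 (0.0713). Leaving out 1 array lowered the count of 2746 to 1527 without unstimulated replicate 1, 1366 without unstimulated replicate 2, 1664 without control replicate 1 and 1736 without control replicate 2. Control and starved cultures differed in medium, and the labels give no harvest time for the control.

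The comparison of stimulated with control cells measured both steps together. Of 8909 genes, 1417 rose and 1172 fell (limma, Benjamini-Hochberg), 54.7% of them higher, and 473 rose and 170 fell by 2-fold or more. Median scaling gave 960 higher and 1292 lower, or 42.6% higher. Under it the median of all genes was -0.13 in stimulated versus unstimulated and -0.11 here, beside -0.01 and -0.01 with the quantile step, so that the balance between rises and falls depends on the normalization. Inmt rose at least 23.7-fold (at least 4.56-fold on its other detected probe), Prelp at least 12.5-fold, Ifi27l2a at least 7.95-fold and Mgp at least 7.01-fold, all from no detection in control cells. Ifit3 rose by 4.29 ± 0.15 (on its other detected probe at least 5.59-fold from no detection in control cells), Cp by 4.06 ± 0.19, Ccl5 by 3.51 ± 0.20, Rsad2 by 3.50 ± 0.15, Mxd4 by 3.37 and Ogn by 3.36 on the log2 scale. Other detected probes gave 3.39 for Cp, 2.88 and 2.55 for Mxd4 and 2.70 and 2.92 for Ogn. The largest falls were those of Prf1 (-3.20 ± 0.40), Zbtb2 (-2.45), Id2 (-2.38), Erich5 (-2.15), Snora69 (-2.11), Prl2c2 (-2.03), Id1 (-2.03) and Slc11a1 (-1.95), with Trim43b and Prrg3 at least 2.71-fold and at least 2.05-fold lower, to no detection. Without control replicate 1 or 2, Prf1 was at -2.54 or -3.83 and Zbtb2 at -1.75 or -3.14, and without stimulated replicate 1 or 2, Id2 was at -1.79 or -2.98. Control replicates 1 and 2 also lay apart for Erich5 (log2 intensities 11.71 and 10.87) and Trim43b (7.54 and 6.49).

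NF-kB genes and chemokines, which camera had not called in unstimulated versus control, passed it here. Of 26 NF-kB genes, 13 rose, and 14 rose and 2 fell adjusted over the list alone (median 0.49, camera adjusted p = 3.02e-05), with Nfkbiz at 3.01, Zc3h12a at 1.88 and Birc3 at 1.31, and Map3k8 at least 2.70-fold higher. Of 10 chemokines, 8 rose and 1 fell, and 9 and 1 adjusted over the list alone (median 1.21, camera adjusted p = 3.87e-06), with Ccl5 at 3.51, Cxcl1 at 2.42, Ccl9 at 2.04 and Cx3cl1 at 1.47. Of 27 interferon-stimulated genes 25 rose and 1 fell by both counts (median 1.76, camera adjusted p = 3.82e-18), with Usp18 at least 6.34-fold higher (at least 1.17-fold on its other probe) and Ifi47 at 3.17. Of 18 MHC class I genes 16 rose by both counts (median 1.04, camera adjusted p = 1.52e-09), with Tapbp at 2.53 (its other detected probe 1.56), Tap2 at 1.79, Psmb9 at 1.71 and Psmb8 at 1.57. Cholesterol genes rose in 14 of 18 by both counts (median 0.89, camera adjusted p = 3.70e-08; Nsdhl 1.77, Mvd 1.54, Lss 1.37, Dhcr7 1.36). FOXO genes rose in 12 of 19, with 1 fall, by both counts (median 0.74, camera adjusted p = 2.18e-05), with Fbxo32 at 2.20 (its other probe 1.16), Pdcd4 at 1.72 and Ccng2 at 1.38, and Pik3ip1 at least 3.59-fold higher. Other detected probes of Pdcd4 gave 1.60 and 1.70, and a further probe was detected in neither group. DNA replication genes fell in 26 of 31, and 29 adjusted over the list alone (median -0.79, camera adjusted p = 2.40e-12), with Ccne1 at -1.11, Mcm3 at -1.07, Prim1 at -1.06 and Mcm7 at -1.01. Mitosis genes fell in 14 of 21, and 17 adjusted over the list alone (median -0.55, camera adjusted p = 7.33e-07), with Ube2c at -1.08, Aurkb at -0.73 and Aurka at -0.69, and Cenpf at least 1.54-fold lower. Ribosome biogenesis genes fell in 11 of 14, and 12 adjusted over the list alone (median -0.60, camera adjusted p = 8.05e-06), with Bop1 at -1.05, Rrp1b at -0.94, Rrp9 at -0.89 and Polr1b at -0.83. Aurka lost its call without control replicate 1 (limma adjusted p = 0.0656), and Rrp9 without control replicate 2 or stimulated replicate 1 (up to 0.0815). These 9 lists also passed with an estimated correlation (adjusted p = 0.0460 for each).

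Another 10 lists passed at the preset correlation only. Among acute phase genes 3 of 6 rose by both counts (camera adjusted p = 0.00103, estimated correlation adjusted p = 0.0863): Cp, Slpi at 1.27, and Lcn2 at least 4.40-fold. Cytokines (7 of 15 rose and 1 fell, both counts, camera adjusted p = 0.0175, estimated correlation adjusted p = 0.131) included Hbegf at -1.50, Il15 at 1.48, Igf2 at 1.38 and Il18 at least 1.11-fold higher. Fatty acid genes (9 of 13 rose, 10 adjusted over the list alone, camera adjusted p = 1.83e-05, estimated correlation adjusted p = 0.0863) included Acss2 at 2.49, Acly at 1.00, Scd2 at 0.92 and Scd1 at 0.91. ATF4 genes (12 of 24 rose, both counts, camera adjusted p = 3.81e-06, estimated correlation adjusted p = 0.0668) included Nupr1 at 2.34, Atf5 at 1.46, Slc7a11 at 1.42 (its 2 other detected probes 0.52 and 0.53) and Dnajb9 at 1.35. Glycolysis and hypoxia genes (12 of 19 rose, both counts, camera adjusted p = 8.05e-06, estimated correlation adjusted p = 0.0668) included Egln3 at 1.43, P4ha2 at 1.36, Slc2a1 at 1.19 and Car9 at least 1.35-fold higher, where the other probes of Egln3 and Car9 were detected in neither group. Immediate early genes (9 of 23 rose and 2 fell, both counts, camera adjusted p = 0.0140, estimated correlation adjusted p = 0.131) included Egr2 at 2.58, Dusp2 at -1.74, Dusp1 at 1.42 and Klf4 at 1.40.

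Matrix genes (7 of 18 rose and 1 fell, 8 and 2 adjusted over the list alone, camera adjusted p = 0.0101, estimated correlation adjusted p = 0.272) included Mmp9 at 1.72, Lox at 1.48, Mmp2 at 1.38 and Plat at 0.87. Receptors and adaptors (4 of 8 rose, 5 adjusted over the list alone, camera adjusted p = 0.0295, estimated correlation adjusted p = 0.131) included Tlr4 at 0.97, its partner Ly96 at 0.69, Cd14 at 0.53 and Ticam1 at least 1.35-fold higher, with the calls of Cd14 and Ticam1 lost under median scaling. Fibroblast markers (6 of 10 rose and 1 fell, both counts, camera adjusted p = 0.00103, estimated correlation adjusted p = 0.0668) included Dcn at 2.21, Pdgfra at 2.13, Pdgfrb at 1.51 and Col3a1 at 1.49. Another probe of Dcn, detected in both groups, gave 2.46. A further probe of Dcn and the other probe of Col3a1, not detected in control cells, gave at least 1.21-fold and at least 1.69-fold. NRF2 targets (1 of 13 rose and 4 fell, both counts, camera adjusted p = 0.0388, estimated correlation adjusted p = 0.131) included Txnrd1 at -1.35, Gclc at -0.74, Nqo1 at 0.73 (its other detected probe 0.21) and Hmox1 at -0.56. SRF and YAP targets did not pass (0 of 14 rose and 2 fell, both counts, adjusted p = 0.633; Ccn1 -0.79, Ankrd1 -0.51), nor did zinc and copper genes (1 of 13 rose and 2 fell, 1 and 1 adjusted over the list alone, adjusted p = 0.930), where Slc30a1 was at -1.48 (-0.84 or -2.13 without stimulated replicate 1 or 2) and Slc39a10 at 0.82. With 1 array left out, the receptor list lost its call without stimulated replicate 2 or control replicate 2 (camera adjusted p up to 0.0944), the matrix list without control replicate 1 (0.0534) and the NRF2 list without control replicate 2 (0.0528). Without at least 1 of the arrays compared, the calls of Ticam1, Cd14, Ly96, Ankrd1, Gclc, Hmox1, Nqo1, Plat and Slc30a1 were lost as well (limma adjusted p up to 0.211, for Hmox1 without stimulated replicate 1). Leaving out 1 array lowered the count of 2589 to 1554 without control replicate 1 and to 1594 without control replicate 2.

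The responses to reduced serum and to S100A8/A9 were then set against each other across genes, which are not independent replicates. Slc39a10 was the 1 gene that fell with reduced serum and rose with S100A8/A9, where independent calls would share 0.958. Nfkbiz and Fas rose in both, 2 genes where independent calls would share 1.2. The fold changes correlated at r = -0.205, whereas simulated groups without any effect gave -0.499 because both responses use the unstimulated arrays. These values of r are not comparable, since the simulation held no serum response. The wide spread of the real serum response across genes weakens r. The covariance of the fold changes, which is not divided by that spread, was -0.0287 beside a simulated -0.0161, a difference of -0.0126. With the unstimulated arrays split between the responses, a check chosen after seeing the data, the covariances were -0.0138 and -0.00647. Stimulated versus control shared 1171 rises and 852 falls with unstimulated versus control, beside 243 and 160 for independent lists. The simulated number was 0 for both, but groups without any effect give almost no calls to share. That number therefore does not measure the overlap that shared controls produce. Their fold changes correlated at r = 0.912 beside a simulated 0.501, with a covariance of 0.305 beside 0.0162. With 1 control array given to each comparison, a split chosen after seeing the data, the covariances were 0.284 and 0.284 and r was 0.803 and 0.800. Calls were not made with 1 control array each, so part of the excess in shared calls may come from the shared controls.

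**Figure D3:**
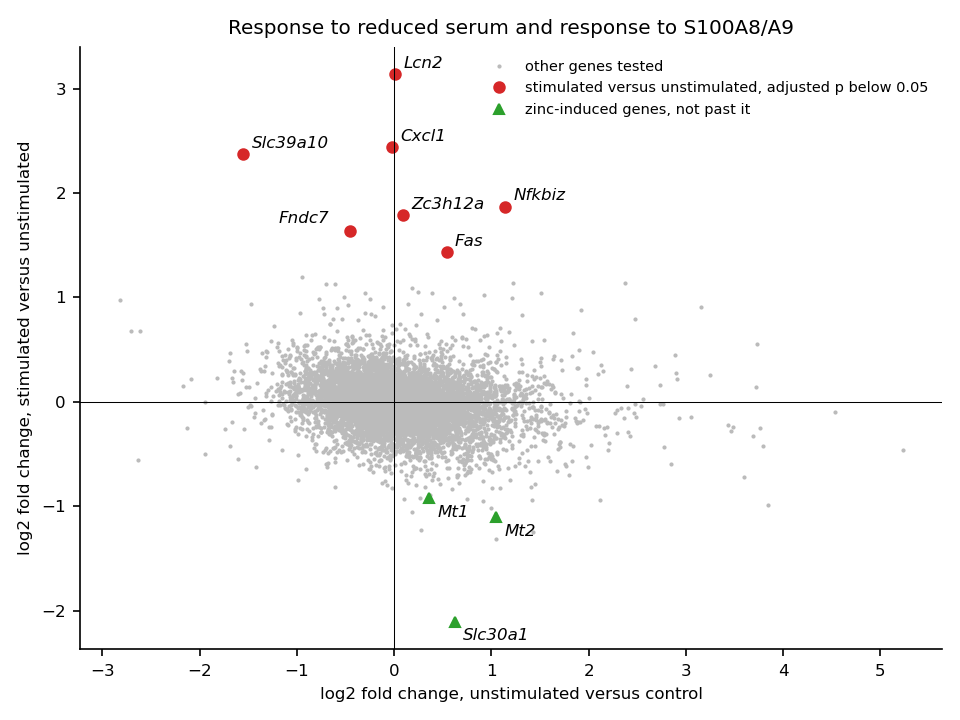
Log2 fold change of 8909 genes in unstimulated versus control (horizontal axis) and in stimulated versus unstimulated cells (vertical axis). Red points are the 7 genes that rose with S100A8/A9, green triangles are zinc-induced genes that lay lower without passing limma's threshold, and Slc39a10 lies at -1.55 and 2.37.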

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

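Probes without a gene name took no part in the comparisons above, and 2 of the 2198 detected ones passed the threshold in stimulated versus unstimulated cells when all 16355 detected probes were tested (limma, Benjamini-Hochberg). They are signals in data that the main tests left out. The larger rose by 3.36 ± 0.20 (SE) on the log2 scale (adjusted p = 0.00137) and was detected on both unstimulated arrays and on 0 control arrays. The other rose by 1.34 ± 0.16 (adjusted p = 0.0330) and was detected on all 6 arrays, with means of 6.70 in control, 8.17 in unstimulated and 9.52 in stimulated cells. In unstimulated versus control, 234 unnamed probes rose and 315 fell, and in stimulated versus control 215 rose and 316 fell.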

How the results depend on the processing

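No gene or list changed direction while past its threshold, but median scaling turned the balance of stimulated versus control from 54.7% to 42.6% higher. The 7 genes that rose with S100A8/A9 passed in every other setting that tested these genes with all arrays in. Splitting the unstimulated or the control arrays was chosen after seeing the data. The count of 7 for stimulated versus unstimulated became 36 with a normexp offset of 50 (25 higher, 11 lower), 44 without background correction and 44 with the authors' deposited log2 values (30 higher and 14 lower each), 15 with median scaling, 17 with detection on all 6 arrays (5 of the 7 were tested), 43 with an intensity trend and robust prior, 11 with array weights, and 4 to 8 without 1 array. Its 6 lists, all upward, became 3 with an estimated correlation, 5 with fry, 4 with detection on all 6 arrays, 9 with the mean of a gene's probes (8 up, 1 down) and 3 to 7 without 1 array; 6 other settings gave 7, adding the glycolysis list downward. For unstimulated versus control, 2746 became 4216 over every detected probe, 633 at 2-fold or more, 1185 with treat at 1.2-fold and 1366 to 2831 without 1 array, and 14 lists became 5 with an estimated correlation and 19 with fry. For stimulated versus control, 2589 became 4021, 643 and 1142 in the same 3 settings and 1554 to 2324 without 1 array, and 19 lists became 9 with an estimated correlation. An array left alone in its group is assumed to vary like the others, with 1 residual degree of freedom fewer. The correlation of the 2 responses moved from -0.205 to -0.0620 with the unstimulated arrays split, to between -0.291 and -0.173 without 1 array, and to -0.251 without a detection filter; the last counts as unmoved only by a band, the SD of the leave-out values, that was adopted after these values had been seen. That of stimulated and unstimulated versus control moved from 0.912 to 0.801 with the control arrays split. Replicate numbers do not pair the samples (correlations of replicate differences -0.0213, -0.0400 and -0.00881), and a replicate block gave 7, 2596 and 2466 genes and 5, 14 and 19 lists. Except where fewer probes, genes or arrays or a size threshold set the number, the cause was not tested. There were 2 arrays per group, and the upper quartile value of each array's probe signals was 2.58 to 2.98 times its median background. The smallest estimate called in stimulated versus unstimulated was 2.71-fold (Fas). Slc30a1, at -2.11 on the log2 scale and so a larger change, was not called, with an SE of 0.35 beside a median of 0.16. Changes of 2-fold or more could therefore be missed.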

Other observations

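The test of leukocyte and endothelial markers was chosen after its values had been seen, the zinc and interferon patterns were noticed in these data before they were tested, and the genes named in the next paragraph were chosen after their values were seen.

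MC38 is labelled a colon carcinoma line, and 0 of 15 epithelial markers were detected on both arrays of any group. Krt8, Krt18 and Epcam were detected on 0 of 6 arrays and Cdh1 on 1. Fibroblast and mesenchymal markers were present, with 9 of 14 detected on both control arrays, Vim among them. Id3 fell at least 2.10-fold, to no detection, with reduced serum (limma adjusted p = 0.000115), as Id1 and Id2 did. Neither Id1 nor Id2 passed in stimulated versus unstimulated cells (limma adjusted p = 0.921 and adjusted p = 0.887). The iron exporter Slc40a1 rose at least 5.62-fold from no detection with reduced serum (limma adjusted p = 1.49e-05). Osr1, a transcription factor gene, rose by 1.42 ± 0.19 with reduced serum (limma adjusted p = 0.00118) and had an estimate of -1.25 ± 0.19 with S100A8/A9 that did not pass (adjusted p = 0.0592). Of 14 leukocyte and endothelial markers with a probe, Coro1a was the 1 gene tested. It rose at least 1.33-fold from no detection in unstimulated versus control (limma adjusted p = 0.0144) and did not pass in the other 2 comparisons.

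S100A8/A9 binds zinc, and 4 zinc genes moved in the pattern that zinc shortage produces: the importer Slc39a10 up, and the zinc-induced Slc30a1, Mt1 and Mt2 down on estimates that passed over their list alone but not over all genes. With reduced serum, Slc39a10 had fallen by 1.55 and Mt2 risen by 1.04. Against control the stimulated cells were at 0.82 for Slc39a10 and -0.06 for Mt2. For these genes, part of the change therefore lies between starved and control levels. Slc30a1 and Mt1 had not passed with reduced serum (limma adjusted p = 0.210 and adjusted p = 0.171). In stimulated versus control both passed over all genes, Slc30a1 at -1.48 (limma adjusted p = 0.0139) and Mt1 at -0.56 (adjusted p = 0.0496). Over the list alone, Mt1 did not pass there (limma adjusted p = 0.0624). If less zinc reached the cells, Mt1, whose value had not been looked at, was predicted to fall. Its log2 change was -0.92 ± 0.19 (SE), the predicted direction. Mt1 is 1 of the 4 genes of the pattern and a metallothionein gene like Mt2. Another cause that lowered both would give the same fall, so it cannot decide for zinc shortage. A misread by single probes stays open, since each of the 4 genes has 1 probe on the array and 0 others could be compared, and so does a direct receptor effect, since no group received zinc with the protein or another chelator. Slc39a10 was higher in all 19 alternative settings and passed in each. By contrast, Slc30a1 was lower in all 18 that tested it and passed in 6, Mt1 was lower in 19 and passed in 5, and Mt2 was lower in 19 and passed in 2. Among these settings, the 2-fold threshold and treat at 1.2-fold repeated the main fit's adjusted p for these genes, so they add no separate check. The deposited log2 values match signals without background correction to within 0.00203, so those 2 settings are 1 check. They are the 2 settings in which Mt2 passed, and Slc30a1 and Mt1 passed in both as well.

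Interferon-stimulated genes rose with reduced serum, without any interferon having been added according to the labels. The quantile normalization is argued against, because the list's median was 1.55 under median scaling. Leukocytes or endothelial cells abundant enough in the starved cultures to supply these transcripts themselves are argued against as well. Of 14 of their markers, 1 (Coro1a) was detected and higher there, and abundant ones such as Lyz2 and Tyrobp were not detected. Cells too few for their markers to be detected are not excluded by this test. Interferon made by the cells cannot be told apart from other triggers: 0 of 32 interferon gene probes were detected in the unstimulated cells and higher there than in control. The bound set beforehand against it was met by 1 Ifna6 probe (log2 change -0.58, limma adjusted p = 0.0276), but that bound was judged wrong after the result was seen, since the 3 other Ifna6 probes were undetected (changes -0.15, -0.21 and 0.08), 1 probe of 1 gene says nothing of the other 18 interferon genes, and a transcript made earlier could be gone by harvest. Reduced serum itself, culture density and medium change, which the design does not separate, stay open as untested.

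The rise of Cxcl1, Nfkbiz, Zc3h12a and the chemokine list is what a ligand of the receptor encoded by Tlr4 is known to induce, and the cells express Tlr4. Bacterial endotoxin in the added protein, which acts through the same receptor, could give the same genes. The 2 cannot be told apart here, since 0 groups received inactivated protein or endotoxin alone. The labels also leave open 6 h more of reduced serum in the stimulated cells. In unstimulated versus control, Nfkbiz and Ccl5 (log2 fold change 2.37) had risen, while Cxcl1 (-0.03) had not and Ccl2 (-0.71) had fallen. What a further 6 h of reduced serum alone would do was not measured. No other technical explanation was tested for this pattern, which passed with an estimated correlation and without any 1 array for the NF-kB and chemokine lists.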
